A study of Homo sapiens with 9 samples.

How the data were processed

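RNA was measured by sequencing in KYSE180, a human esophageal squamous cell carcinoma line that the series title describes as KDM6A-deficient. All 9 libraries came from cells given 6 Gy of ionizing radiation. They form 3 groups of 3 libraries: a luciferase control hairpin (shluc) and 2 hairpins against EZH2 (shEZH2#1 and shEZH2#3). The titles and the design text speak of a knockdown by short hairpin RNA, whereas a genotype label of the EZH2 libraries says knockout; the groups were taken from the titles. No label says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. No unirradiated sample was analysed here.

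Per the labels' protocols, polyadenylated RNA was selected, fragmented and made into dUTP-stranded libraries with a TruSeq Stranded mRNA kit. The submitters' processing notes name fastp, HISAT2 and StringTie and the build GRCh38 (hg38), with no versions. The counting step, its annotation release, its strand setting and its treatment of multiply mapped reads are not given in the sources used here. The deposited values are estimated counts per Ensembl gene, with no normalization: totals differ between libraries, and 14.7 to 18.5% of nonzero values carry decimals. The table of the whole series held the same values as the files of the single libraries for all 57905 genes. Because the strand setting is unknown, overlapping and antisense genes, and genes with near-identical copies, are uncertain.

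Gene symbols were matched by Ensembl identifier: 51996 identifiers had a symbol in a naming table, 342 more in GENCODE 29, and 5567 had none. Identifiers without a symbol took 6.43 to 23.08% of counts. Most of that share came from 2 identifiers, ENSG00000266658 and ENSG00000272060, which together took 5.97 to 22.58% of the counts of a library. Positions are those of GENCODE 29 on GRCh38. GC content and length came from the longest GENCODE 29 transcript of each gene, protein-coding where the gene had such a transcript, and covered 97.7% of tested genes.

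The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, genes were filtered with filterByExpr on the 3 groups (13252 genes kept), and all 9 libraries entered a quasi-likelihood fit with a mean per group. The common dispersion was 0.0315, a biological coefficient of variation of 0.177. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold. The contrasts were each hairpin against shluc, the mean of both hairpins against shluc, and shEZH2#1 against shEZH2#3. A gene was called in both hairpins when it passed in each with the same sign. Adjusted p-values of genes are from this test unless another tool is named. Errors of log2 fold changes are approximate standard errors (SE). Each is the size of the fold change without edgeR's shrinkage, divided by the square root of the test's F statistic. The printed fold changes carry that shrinkage, so the match may be loose for genes with few counts. Errors of counts scaled to a common library total (CPM) are standard deviations (SD, n = 3).

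The 35 gene lists were fixed before the data were examined, and 1005 of their 1042 entries were found. A symbol held by several lists counts once in each. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Estimated correlation and fry served as other set tests. Unless another tool is named, a list is called by camera, which compares its members with the other genes, whereas fry tests the members alone. Genes named in the text followed a rule fixed at the same time. It took 9 genes of the Polycomb and p53 pathways, then the 12 highest and 12 lowest mean fold changes among genes called in both hairpins with a mean CPM of at least 5 and all 6 knockdown libraries outside the shluc range. It also took the 4 largest rises and falls per hairpin that differed between hairpins, and up to 4 members per list called in both hairpins, or the 2 most abundant where there were none. Some of the genes so chosen are not reported here.

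Alternatives planned before the data were examined were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, fits of only the groups compared, the replicate number as a block, a minimum fold of 2, and each library left out in turn. After the data were seen, a correction for GC content and length was added (a smooth per library with a span of 0.3, as an offset), as were fits without the 2 abundant unnamed genes, without these and the mitochondrially encoded genes, and without shluc replicate 2 and shEZH2#3 replicate 1. An estimated correlation was then also combined with that correction and with libraries left out.

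The tests were tried on simulated counts with 50 changed genes per fold size. At a simulated log2 fold of 1, 56% were recovered for shEZH2#1 against shluc and 56% for shEZH2#3 against shluc (12807 genes), and 54% between the hairpins (12817 genes). At a log2 fold of 2 the shares were 86%, 92% and 90%. Where a GC trend alone was simulated around 200 genes with a log2 fold of 1 (12864 genes), the fit of the mean of both hairpins called 2423 unchanged genes without the correction and 15 with it, and recovered 81% and 72% of the changed genes. Unchanged groups against freshly drawn controls were simulated 20 times for the comparison of the hairpins.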

Results

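Gene expression after 6 Gy of ionizing radiation was compared between KYSE180 cells with a control hairpin and cells with either of 2 hairpins against EZH2, the methyltransferase subunit of Polycomb repressive complex 2. The comparison addresses what lowering EZH2 does to transcription in irradiated cells of this KDM6A-deficient line; KDM6A is a demethylase of the histone mark that EZH2 writes. Library totals were 19508444, 18923610 and 18563879 estimated counts in shluc, 15733529, 16946226 and 14958011 in shEZH2#1, and 21152006, 18366510 and 20366699 in shEZH2#3 (replicates 1 to 3). A count of 1 corresponded to 0.0473 to 0.0669 CPM. Libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 5.43 to 57.95, so no library was left out as a copy of another.

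EZH2 (ENSG00000106462, chromosome 7, 148807383 to 148884321) stood at 19.3 ± 0.89 CPM in shluc, 10.1 ± 2.41 in shEZH2#1 and 9.94 ± 0.989 in shEZH2#3 (SD, n = 3). All 6 knockdown libraries lay below all 3 controls. The log2 fold change was -0.94 ± 0.18 with shEZH2#1 (adjusted p = 0.00163) and -0.96 ± 0.18 with shEZH2#3 (adjusted p = 0.000433), and the mean of both left 51.8% of the control level. The hairpins did not differ detectably in EZH2 (log2 fold change 0.02 ± 0.19, adjusted p = 0.943). Of the partner subunits, EED fell with shEZH2#3 (-0.85 ± 0.21, adjusted p = 0.00352) and had -0.26 ± 0.21 with shEZH2#1 (adjusted p = 0.411). SUZ12 and the paralog EZH1 passed the test with neither hairpin. KDM6A was low in all groups (3.61 CPM on average) and had -0.13 ± 0.25 and -0.19 ± 0.24, past the threshold in neither. KDM6B, a related demethylase, rose with shEZH2#3 (0.94 ± 0.15, adjusted p = 0.000118) and had 0.26 ± 0.15 with shEZH2#1. After a correction for GC content and length, added after the data were seen, EZH2 passed with both hairpins (-0.73, adjusted p = 0.00399, and -0.56, adjusted p = 0.0133), and EED and KDM6B did not pass (adjusted p = 0.054 and 0.05 with shEZH2#3).

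**Figure D1:**
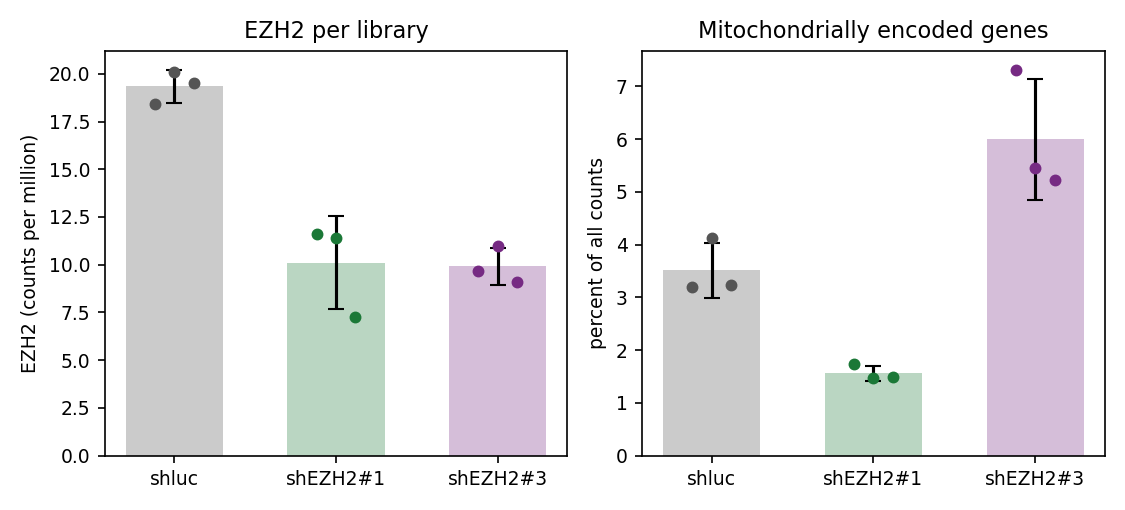
EZH2 in CPM (left) and the percent of counts from mitochondrially encoded genes (right) in each library; points are libraries, bars are group means and error bars are SD (n = 3). EZH2 means were 19.3 in shluc, 10.1 in shEZH2#1 and 9.94 in shEZH2#3, and mitochondrial shares were 3.51%, 1.56% and 6.0%.

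In shEZH2#1 libraries, the lists of interferon response and p53 response genes rose, while those of mitosis genes and mitochondrially encoded genes fell. These camera calls did not hold with an estimated correlation (adjusted p = 0.201 for the first 3 lists and 0.507 for the mitochondrial list). CPT1B, the muscle-type carnitine palmitoyltransferase, rose from 2.69 to 21.5 CPM (log2 fold change 3.00 ± 0.24). ACSL4, an acyl-CoA synthetase for polyunsaturated fatty acids, rose by 3.07 ± 0.34. The immediate early transcription factor EGR1 fell by 1.53 on the log2 scale. In all, 2523 of 13252 genes passed the test, 1478 higher and 1045 lower. Other large rises that also differed from shEZH2#3 were PLA2G4B (2.85 ± 0.29), ADAMTS10 (2.46 ± 0.23) and DNAH1 (2.38 ± 0.28); PLA2G4B overlaps a neighbouring gene's read-through transcript and is uncertain. Falls of the same kind were SUSD2 (-1.50 ± 0.22), MAPK4 (-1.43 ± 0.20) and SSR1 (-1.42 ± 0.15). CDKN2A rose by 0.58 ± 0.18 (adjusted p = 0.0274), a call lost after the GC and length correction (adjusted p = 0.696). With that correction CDKN2A was called lower with shEZH2#3 (-0.48, adjusted p = 0.0203) and differed between the hairpins (0.58, adjusted p = 0.00614). The count was 1159 without shEZH2#1 replicate 3, 1344 without shEZH2#1 replicate 2 and 1550 without shluc replicate 2. With the GC and length correction the split turned to 1089 higher and 1311 lower, and without the 2 abundant unnamed genes it was 1707 and 779.

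In shEZH2#3 libraries, mitosis genes fell more widely, and mitochondrially encoded genes, inflammatory cytokines and ribosomal protein genes rose. No call of these 4 lists held with an estimated correlation (camera adjusted p = 0.133, 0.564, 0.47 and 0.762, in that order), and that of ribosomal protein genes was also lost without shluc replicate 2 or shEZH2#3 replicate 1. DHRS3, a retinaldehyde reductase, rose from 3.51 to 26.1 CPM (2.91 ± 0.25). Among mitochondrially encoded RNAs the rule named MT-ATP8 (2.97 ± 0.51) and MT-ND4L (2.81 ± 0.49), and the nuclear copy MTATP6P1 (2.87 ± 0.53) shares reads with a mitochondrial gene and is uncertain. The sizes of these rises rested on replicate 1 of shEZH2#3, where MT-ATP8 stood at 530 CPM against 82 and 66 in the other libraries of the group and 22.8 to 36 in shluc. The chaperone HSPA8 fell by 1.92 on the log2 scale, SERPINE2 had -1.70 ± 0.27 and REXO5 -1.69 ± 0.21. AMIGO3 had -3.66 ± 1.15, with control libraries between 0 and 33.2 CPM. In all, 5861 genes passed, 3237 higher and 2624 lower. With upper quartile scaling the split was 2421 higher and 3720 lower, and the median of all genes moved from -0.01 to -0.18. The GC and length correction lowered the count to 3206, of which 2071 were shared with the uncorrected calls.

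With both hairpins ACSL4, CPT1B, SPARC and BIK were higher than in shluc, and mitosis genes such as MKI67 were lower. Among genes called in both with a mean of at least 5 CPM and all 6 knockdown libraries outside the shluc range, the 12 largest rises were ACSL4 (mean log2 fold change 2.86 ± 0.32), IGFN1 (2.33 ± 0.44), CPT1B (2.20 ± 0.22), ADAMTS10 (2.09 ± 0.21), DHRS3 (2.08 ± 0.23), SPARC (1.94 ± 0.36), GPNMB (1.89 ± 0.29), DNAH1 (1.62 ± 0.25), SPATA2L (1.53 ± 0.18), FXYD3 (1.46 ± 0.22), ACTA2 (1.44 ± 0.20) and BIK (1.42 ± 0.17). SPARC encodes a matrix protein and BIK a pro-apoptotic BH3-only protein. The floor of 5 CPM was a mean over all 9 libraries, and several of these genes were low in shluc. ACSL4 stood there at 0.399 to 1.47 CPM, IGFN1 at 0.0461 to 2.59 and SPARC at 0.599 to 2.49, so the sizes of these folds rest on low control levels. Within the same limits the 12 largest falls were LAMA1 (-1.48 ± 0.18), MKI67 (-1.28 ± 0.15), KPNA2 (-1.26 ± 0.13), QSER1 (-1.23 ± 0.18), KIF20A (-1.21 ± 0.14), NEK2 (-1.18 ± 0.15), RBM3 (-1.16 ± 0.17), ITPR1 (-1.14 ± 0.17), GLCCI1 (-1.14 ± 0.23), CEMIP2 (-1.13 ± 0.14), ANLN (-1.12 ± 0.16) and SPAG5 (-1.12 ± 0.13). MKI67 encodes the proliferation marker Ki-67, KIF20A a mitotic kinesin, NEK2 a centrosomal kinase and ANLN a cytokinesis scaffold. After the GC and length correction DNAH1, ACTA2, GLCCI1 and ANLN no longer passed with both hairpins (adjusted p = 0.128 for DNAH1 with shEZH2#3, and 0.0586 for ACTA2, 0.0974 for GLCCI1 and 0.0751 for ANLN with shEZH2#1). The fold of ACTA2 hardly moved (0.68 to 0.63), while those of DNAH1 (0.86 to 0.55), GLCCI1 (-0.91 to -0.62) and ANLN (-0.66 to -0.32) shrank.

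A total of 1491 genes were called in both hairpins in the same direction, 1059 higher and 432 lower, and 111 in opposite directions. Leaving out each library in turn gave 657 to 1951 genes in the same direction. Independent lists of these sizes would share 361 higher and 207 lower genes, and unchanged groups against common controls shared 0.2 and 0.15 on average. These simulated groups had only 1.35 and 1 calls per hairpin on average, so their overlap is no measure for lists of the observed sizes. The correlation of fold changes across genes, which are not independent replicates, was 0.54 against a simulated 0.48. The covariance was 0.235 against a simulated 0.0419, and the difference of 0.193 estimates what the hairpins share beyond the controls, a common GC trend included. After the GC and length correction the covariance was 0.111 and the correlation 0.38, with no simulated value for that fit. The simulated controls carried only the fitted spread, and the 3 controls cannot be split into parts of at least 2 libraries. Control error beyond that spread may thus still be part of the difference. The GC and length correction changed the split of shared calls to 361 higher and 421 lower, with 405 genes in common with the uncorrected calls. For the mean of both hairpins 4804 genes passed, 2600 higher and 2204 lower, and upper quartile scaling gave 2284 and 2983. The GC and length correction lowered the count to 2472, and leaving out shluc replicate 2 to 2649.

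**Figure D2:**
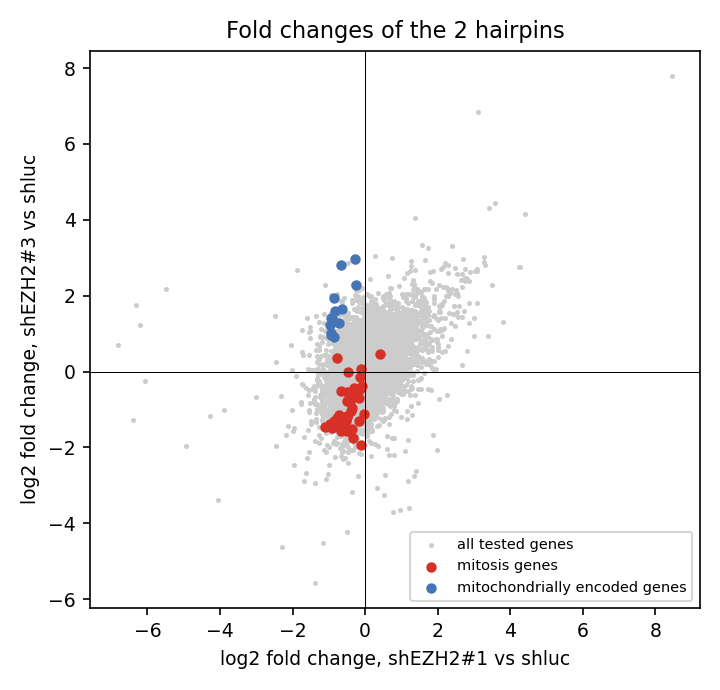
Log2 fold change against shluc with shEZH2#1 (horizontal) and shEZH2#3 (vertical) for the 13252 tested genes in grey, mitosis genes in red and mitochondrially encoded genes in blue. Medians of the mitosis list were -0.50 and -1.21, and those of the mitochondrial list -0.85 and 1.42.

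Fold changes followed GC content. Across genes the rank correlation of fold change with GC content was 0.47 for shEZH2#1, 0.69 for shEZH2#3 and -0.41 between the hairpins. With transcript length it was -0.33, -0.35 and 0.12, in that order. The tenth of genes with the lowest GC content (median 37.5%) had a median log2 fold change of -0.27 with shEZH2#1 and -0.60 with shEZH2#3, and the tenth with the highest (64.8%) had 0.47 and 0.70. Groups did not overlap in this trend: per-library rank correlations with GC content were -0.69 to -0.39 in shluc, -0.25 to 0.25 in shEZH2#1 and 0.37 to 0.64 in shEZH2#3. No label gives a batch, so no within-batch value could be had.

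**Figure D3:**
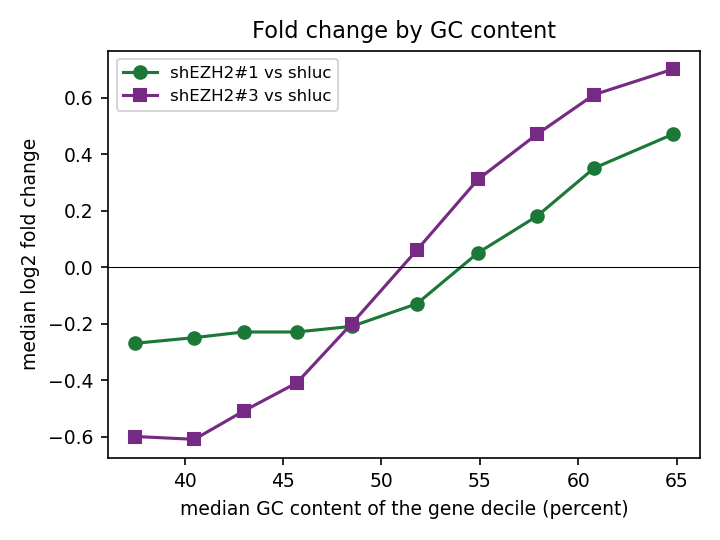
Median log2 fold change (vertical) in 10 equal groups of genes ordered by GC content (horizontal, median percent of each group), for shEZH2#1 (circles) and shEZH2#3 (squares) against shluc. In the groups of lowest and highest GC content the medians were -0.27 and 0.47 with shEZH2#1, and -0.60 and 0.70 with shEZH2#3.

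Mitosis genes were lower with both hairpins. Of 42 tested members 16 fell with shEZH2#1 and 34 with shEZH2#3, none rose, and 14 fell in both, among them MKI67, KIF20A, NEK2 and ANLN. Adjusted over the list alone, 21 fell with shEZH2#1, and 36 fell and 2 rose with shEZH2#3. List medians were -0.50 and -1.21, with camera adjusted p = 1.15e-06 and 6.65e-12. With an estimated correlation neither call held (adjusted p = 0.201 and 0.133). After the GC and length correction the medians were -0.32 and -0.76, with camera adjusted p = 4.14e-06 and 2.25e-16 (adjusted p = 0.109 and 0.0308 with an estimated correlation). Replication and E2F genes were not called as a list by camera: 1 rose and 6 fell of 42 with shEZH2#1, and 7 rose and 17 fell with shEZH2#3 (adjusted over the list alone, 3 and 6, then 7 and 17; camera adjusted p = 0.409 and 0.165). Fry called the list lower with shEZH2#3 (adjusted p = 0.0216), though not with shEZH2#1 (0.136). RRM1 (-0.76 ± 0.13), RRM2 (-0.67 ± 0.12) and TYMS (-0.52 ± 0.12), which supply nucleotides, fell in both, and E2F1 rose (0.76 ± 0.15), though after the GC and length correction RRM1 did not pass with shEZH2#1 and E2F1 passed with neither hairpin.

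Genes of the p53 response rose with shEZH2#1: 10 of 28 rose and none fell, or 12 adjusted over the list alone (camera adjusted p = 0.00509; adjusted p = 0.201 with an estimated correlation). With shEZH2#3, 10 rose and 1 fell, over all genes and adjusted over the list alone alike (camera adjusted p = 0.202; fry adjusted p = 0.00426). The lists did not differ detectably between hairpins (camera adjusted p = 0.592). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 140 ± 17.3 CPM to 225 ± 28 and 283 ± 8.12 (0.68 ± 0.15 and 1.02 ± 0.15). BAX (0.98 ± 0.16), PHLDA3 (0.95 ± 0.16), FDXR (0.93 ± 0.16) and BBC3 (0.89 ± 0.17) rose in both; BBC3 and, with shEZH2#3, FDXR lost the call after the GC and length correction. MDM2, which p53 induces, fell with shEZH2#3 (-0.75 ± 0.24, adjusted p = 0.0165) and had -0.18 ± 0.23 with shEZH2#1; the fall was not called after that correction (adjusted p = 0.64). Apoptosis regulators had 7 rises and 2 falls of 29 with shEZH2#1 and 9 and 4 with shEZH2#3, the same counts adjusted over the list alone (camera adjusted p = 0.208 and 0.568; fry adjusted p = 0.0261 and 0.0103, higher); with shEZH2#3 the list's median was -0.08 and its mean 0.15. The pro-apoptotic genes BIK, BAD (1.26 ± 0.18), BMF (1.21 ± 0.19) and BAX rose in both. After the GC and length correction this list passed with both hairpins by camera at the preset correlation (camera adjusted p = 0.0182 and 0.0244), and with neither at an estimated one (adjusted p = 0.253 and 0.314).

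Interferon response genes rose with shEZH2#1, with 8 rises and no fall among 37 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0022; adjusted p = 0.201 with an estimated correlation). With shEZH2#3, 9 rose and 7 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.972), and the hairpins differed (camera adjusted p = 0.00291; adjusted p = 0.202 with an estimated correlation). ISG20 (1.18 ± 0.19), IRF9 (1.08 ± 0.16), IFI6 (0.97 ± 0.19) and IFI35 (0.72 ± 0.15) rose in both; of these, ISG20 passed with shEZH2#3 after the GC and length correction. Cytokines and NF-kB targets rose with shEZH2#3: 14 rose and 2 fell of 26, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00168; adjusted p = 0.47 with an estimated correlation). With shEZH2#1, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.53). CXCL6 (2.30 ± 0.53), CXCL1 (1.39 ± 0.28), RELB (0.97 ± 0.15) and CSF1 (0.78 ± 0.15) rose in both, the chemokines from low levels; RELB and CSF1 did not pass with shEZH2#1 after the correction. MHC class I genes had 5 rises and 2 falls of 19 with shEZH2#1 and 9 and 3 with shEZH2#3 (6 and 5, then 11 and 3, adjusted over the list alone; camera adjusted p = 0.438 and 0.165; fry adjusted p = 0.311 and 0.0263, higher). The class I regulator NLRC5 rose (0.96 ± 0.13), as did TAPBPL (0.69 ± 0.16), while the chaperone CANX fell (-0.76 ± 0.13). Of these 3 genes, CANX passed with both hairpins after the correction. Nucleic acid sensing genes had 0 rises and 1 fall of 11, then 3 and 2 (0 and 1, then 3 and 4, adjusted over the list alone; camera adjusted p = 0.908 and 0.972); ADAR fell with shEZH2#1 (-0.63 ± 0.17) and IRF3 rose with shEZH2#3 before the correction (0.77 ± 0.15). Only 3 of 13 MHC class II genes were tested, of which HLA-DMA rose with shEZH2#3 (1.11 ± 0.19).

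Mitochondrially encoded genes moved in opposite directions. With shEZH2#1, 9 of 13 fell (10 adjusted over the list alone; median -0.85, camera adjusted p = 2.72e-05). With shEZH2#3 all 13 rose, as they did adjusted over the list alone (median 1.42, camera adjusted p = 9.83e-07). Neither call held with an estimated correlation (adjusted p = 0.507 and 0.564). MT-CO1 had -0.93 ± 0.16 and 0.97 ± 0.16, and MT-CO3 -0.94 ± 0.16 and 1.02 ± 0.16. The list's share of counts was 3.51% ± 0.53 in shluc, 1.56% ± 0.14 in shEZH2#1 and 6.0% ± 1.14 in shEZH2#3 (SD, n = 3). The 2 abundant unnamed genes, in contrast, took 8.23% ± 1.18, 19.38% ± 3.4 and 8.54% ± 2.84. Ribosomal protein genes rose with shEZH2#3, 23 of 51 with no fall, over all genes and adjusted over the list alone alike (camera adjusted p = 0.00465; adjusted p = 0.762 with an estimated correlation and 0.189 by fry). With shEZH2#1, 8 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.208). RPS9 (0.95 ± 0.18) and RPL8 (0.69 ± 0.15) rose in both, and RPS9 passed with both after the GC and length correction; genes of this class share reads with pseudogenes. The call with shEZH2#3 was lost without shluc replicate 2 (adjusted p = 0.0609) and without shEZH2#3 replicate 1 (adjusted p = 0.0847), while the list was called higher with shEZH2#1 without shluc replicate 3 (camera adjusted p = 0.00376; adjusted p = 0.659 with an estimated correlation).

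Known targets of Polycomb did not rise as lists, among the members that were tested. These were 23 of 39 HOX genes, 40 of 91 developmental transcription factors and 23 of 30 genes described as repressed by EZH2 in tumours. Genes below the expression filter were left out, so targets that stayed silent in all groups were not tested. Of 23 HOX genes 0 passed with shEZH2#1, while 3 rose and 1 fell with shEZH2#3 (1 and 0 adjusted over the list alone; camera adjusted p = 0.87 and 0.801), and the GC and length correction left 0 rises and 1 fall, then 1 and 3. HOXC10 had -0.19 ± 0.13 and 0.13 ± 0.13, and HOXB13 -0.21 ± 0.15 and 0.77 ± 0.15. Of 40 developmental transcription factors 2 rose and 1 fell with shEZH2#1, and 9 rose and 5 fell with shEZH2#3 (1 and 1, then 8 and 5, adjusted over the list alone; camera adjusted p = 0.53 and 0.972). The correction turned this balance to 1 rise and 6 falls with shEZH2#1 and 2 and 9 with shEZH2#3 (camera adjusted p = 0.0616 and 0.0843), and the list was called lower for the mean of both (camera adjusted p = 0.023; adjusted p = 0.459 with an estimated correlation). BARX1 (0.80 ± 0.18) and PITX1 (0.63 ± 0.15) rose in both, but after the GC and length correction BARX1 did not pass with shEZH2#3 and PITX1 had a mean of -0.01. Among 23 genes described as repressed by EZH2 in tumours, 4 rose and 3 fell with shEZH2#1 and 4 rose and 2 fell with shEZH2#3 (4 and 5, then 3 and 2, adjusted over the list alone; camera adjusted p = 0.704 and 0.568), and the correction gave 1 and 5, then 4 and 5. KLF2 (0.89 ± 0.28) rose in both, and lost the call after that correction. PRC2 subunits had 0 rises with either hairpin, and 2 and 5 falls of 12, the same adjusted over the list alone (camera adjusted p = 0.111 and 0.1, fry adjusted p = 0.0271 and 0.00901, lower). This list holds EZH2, the target of the hairpins, so part of its fall was set by the design. It was not tested without EZH2. The correction left 1 and 3 falls (camera adjusted p = 0.238 and 0.224). EZH2 and RBBP4 (-0.61 ± 0.12) fell in both, RBBP4 not after the correction. PRC1 subunits had 2 rises and 1 fall of 21, then 4 and 2 (3 and 3, then 4 and 1, adjusted over the list alone; camera adjusted p = 0.517 and 0.753; fry adjusted p = 0.0358, lower, and 0.0568), with L3MBTL2 (0.56 ± 0.14) and CBX2 (0.50 ± 0.13) higher in both before that correction. The demethylase and KMT2C/D list had 0 rises and 3 falls of 12, then 1 and 5 (the same adjusted over the list alone; camera adjusted p = 0.208 and 0.165), and CREBBP fell in both (-0.66 ± 0.15).

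DNA repair lists had no shared call by camera. Fry called end joining genes (adjusted p = 0.0467 and 0.0134) and damage checkpoint genes (0.0467 and 0.00426) lower with both hairpins. End joining genes had medians of -0.27 and -0.38 before the GC and length correction and -0.10 and -0.33 after it. Damage checkpoint genes went from -0.13 and -0.50 to 0.03 and -0.08. Homologous recombination and Fanconi genes went from -0.24 and -0.38 to -0.01 and -0.07. Camera called none of the 3 lists after the correction, and fry was not run with it. Homologous recombination and Fanconi genes had 3 rises and 5 falls of 39 with shEZH2#1 and 5 and 11 with shEZH2#3, the same adjusted over the list alone (camera adjusted p = 0.154 and 0.0539); this list was called lower with shEZH2#3 without shluc replicate 3 (camera adjusted p = 0.0364; adjusted p = 0.666 with an estimated correlation), among others, and by fry with all 9 libraries (adjusted p = 0.0127). EXO1 (-0.68 ± 0.16) and EME1 (-0.66 ± 0.18) fell and FANCE (0.80 ± 0.15) and XRCC3 (0.51 ± 0.13) rose in both, of which FANCE passed with both hairpins after the GC and length correction. End joining genes had 3 rises and 3 falls of 20, then 3 and 7 (3 and 3, then 4 and 8, adjusted over the list alone; camera adjusted p = 0.46 and 0.382). PRKDC, the catalytic subunit of DNA-dependent protein kinase, fell with each hairpin (-0.92 ± 0.20 and -1.09 ± 0.20), before and after the correction. Damage checkpoint genes had 2 rises and 3 falls of 22, then 3 and 8, the same adjusted over the list alone (camera adjusted p = 0.3 and 0.0636). RAD9A rose in both before the correction (0.65 ± 0.15).

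ITGB4 and FN1 rose with both hairpins before and after the GC and length correction. With all 9 libraries and before it, camera called the squamous, mesenchymal and epithelial lists with neither hairpin against shluc. By fry, squamous differentiation genes were called higher with both hairpins (adjusted p = 0.0464 and 0.00521) and mesenchymal genes with each in opposite directions (0.0467 and 0.00976). Basal squamous and epithelial adhesion genes were called higher by fry with shEZH2#1 (0.0464 and 0.0467), and TGF-beta, BMP and WNT feedback genes were called lower (0.0261). Basal squamous genes had 4 rises and 2 falls of 16 with shEZH2#1 and 3 and 3 with shEZH2#3 (4 and 3, then 4 and 5, adjusted over the list alone; camera adjusted p = 0.281 and 0.844). ITGB4 (1.02 ± 0.14) and ITGA3 (0.70 ± 0.14) rose and ITGB1 (-0.68 ± 0.13) fell in both, though ITGB1 did not pass with shEZH2#1 after the correction (adjusted p = 0.0717). Squamous differentiation genes had 3 rises and 0 falls of 17, then 10 and 2 (3 and 0, then 10 and 4, adjusted over the list alone; camera adjusted p = 0.154 and 0.165). TGM1 (0.82 ± 0.15), PRSS27 (0.79 ± 0.20) and EVPL (0.76 ± 0.15) rose in both, but none of the 3 did so after the correction. Mesenchymal genes had 3 rises and 9 falls of 27 with shEZH2#1 and 13 and 3 with shEZH2#3 (3 and 10, then 14 and 4, adjusted over the list alone; camera adjusted p = 0.208 and 0.105); the correction made the list lower with shEZH2#1 (camera adjusted p = 0.0252), and it was called higher with shEZH2#3 without shluc replicate 2 and shEZH2#3 replicate 1 (camera adjusted p = 0.0258). Neither call held with an estimated correlation (adjusted p = 0.511 and 0.374). FN1, which encodes fibronectin, rose from 121 to 309 and 282 CPM (1.29 ± 0.16), ITGA5 rose (0.86 ± 0.14) and THBS1 fell (-0.81 ± 0.13); ITGA5 lost the call with shEZH2#1 after the correction (adjusted p = 0.0828). Epithelial adhesion genes had 4 rises and 2 falls of 20, then 10 and 6 (6 and 3, then 10 and 7, adjusted over the list alone; camera adjusted p = 0.208 and 0.609). KRT19 fell from a low level (7.03 CPM in shluc, -2.29 ± 0.40), while TJP3 (1.22 ± 0.14), CLDN4 (0.96 ± 0.13) and CRB3 (0.76 ± 0.16) rose. None of the last 3 passed with both hairpins after the correction (adjusted p = 0.0613 for TJP3 with shEZH2#1, and 0.0523 for CLDN4 and 0.923 for CRB3 with shEZH2#3). TGF-beta, BMP and WNT feedback genes had 1 rise and 6 falls of 25, then 6 and 8 (1 and 8, then 6 and 8, adjusted over the list alone; camera adjusted p = 0.154 and 0.63), with DKK3 (1.68 ± 0.28) higher and BMP4 (-2.15 ± 0.41) and TGFB2 (-0.85 ± 0.19) lower in both. With the correction TGFB2 passed with neither hairpin (adjusted p = 0.133 and 0.166), and this list was lower with shEZH2#1 (camera adjusted p = 0.021; adjusted p = 0.324 with an estimated correlation).

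With all 9 libraries and before the GC and length correction, camera called metabolic and stress lists with neither hairpin. By fry, hypoxia and glycolysis genes were called lower with shEZH2#1 and higher with shEZH2#3 (adjusted p = 0.0358 and 0.00426), unfolded protein and immediate early genes lower with shEZH2#1 (0.0202 and 0.0467) and NRF2 targets with shEZH2#3 (0.0161). Hypoxia and glycolysis genes had 2 rises and 6 falls of 31 with shEZH2#1 and 15 and 2 with shEZH2#3 (2 and 8, then 15 and 2, adjusted over the list alone; camera adjusted p = 0.154 and 0.0539). With the correction this list was called lower with shEZH2#1 (camera adjusted p = 0.0252) and higher with shEZH2#3 (camera adjusted p = 0.0244), and it was also called higher with shEZH2#3 without shluc replicate 2 (camera adjusted p = 0.023) or without shEZH2#3 replicate 1 (camera adjusted p = 0.0242). None of these calls held with an estimated correlation (adjusted p = 0.593, 0.43, 0.366 and 0.206, in that order). LDHA fell (-0.68 ± 0.13) and TPI1 (0.66 ± 0.16) and PFKFB4 (0.57 ± 0.12) rose in both, but LDHA with shEZH2#3 (adjusted p = 0.106) and TPI1 with shEZH2#1 (adjusted p = 0.0606) did not pass after the correction. Sterol synthesis genes had 3 rises and 3 falls of 24, then 11 and 5 (4 and 4, then 11 and 5, adjusted over the list alone; camera adjusted p = 0.694 and 0.609). PMVK (0.81 ± 0.16), MVK (0.78 ± 0.13) and MVD (0.58 ± 0.15) rose in both; none of the 3 passed with both hairpins after the correction. Unfolded protein and amino acid stress genes had 2 rises and 8 falls of 30, then 10 and 8 (2 and 10, then 11 and 9, adjusted over the list alone; camera adjusted p = 0.119 and 0.801). They were called lower with shEZH2#1 after the correction (camera adjusted p = 0.0043) or without shluc replicate 2 (camera adjusted p = 0.0424), in neither case with an estimated correlation (adjusted p = 0.109 and 0.215). The asparagine synthetase ASNS (-0.90 ± 0.15) and the endoplasmic reticulum chaperones HSPA5 (-0.86 ± 0.13) and HSP90B1 (-0.83 ± 0.13) fell, and TRIB3 (0.83 ± 0.14) rose; HSPA5 and TRIB3 lost the call with shEZH2#1 after the correction (adjusted p = 0.0817 and 0.0934). NRF2 targets had 4 rises and 3 falls of 29, then 7 and 10 (5 and 3, then 7 and 11, adjusted over the list alone; camera adjusted p = 0.438 and 0.218), with TXNRD1 (-0.85 ± 0.13) and SRXN1 (-0.57 ± 0.12) lower and HMOX1 (0.56 ± 0.13) higher, the last not with shEZH2#3 after the correction (adjusted p = 0.915). Immediate early genes had 1 rise and 6 falls of 28, then 8 and 5 (1 and 8, then 8 and 5, adjusted over the list alone; camera adjusted p = 0.208 and 0.568), with JUND (0.88 ± 0.16) higher and EREG (-0.77 ± 0.16) and ATF3 (-0.68 ± 0.15) lower. The correction made this list lower with shEZH2#1 (camera adjusted p = 0.0383; adjusted p = 0.675 with an estimated correlation), and ended the calls of JUND with shEZH2#1 (adjusted p = 0.659) and EREG with shEZH2#3 (adjusted p = 0.363). Replication-dependent histone genes, whose RNAs mostly lack poly(A) tails, had 4 rises and 0 falls of 16, then 2 and 0 (5 and 0, then 2 and 0, adjusted over the list alone; camera adjusted p = 0.0992 and 0.801), and were called higher with shEZH2#1 without shEZH2#1 replicate 1 (camera adjusted p = 0.00587; adjusted p = 0.359 with an estimated correlation). H1-2 rose with shEZH2#1 (0.81 ± 0.16), a call lost after the correction (adjusted p = 0.281).

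Markers of other cell types gave no list call by camera, while fry called fibroblast markers higher with shEZH2#3 (adjusted p = 0.0213). Fibroblast markers had 2 rises and 1 fall of 8 with shEZH2#1 and 5 and 1 with shEZH2#3, the same adjusted over the list alone (camera adjusted p = 0.438 and 0.268), with ACTA2 and DCN (0.93 ± 0.22) higher in both. Of 4 tested blood cell markers 0 passed with shEZH2#1 and 2 rose with shEZH2#3, among them CSF1R (0.95 ± 0.27). Of 4 endothelial markers 1 rose and 1 fell with shEZH2#1 and 4 rose with shEZH2#3, and EGFL7 rose in both (0.72 ± 0.15). Corrected for GC content and length, CSF1R did not pass (adjusted p = 0.0881 with shEZH2#3), nor did EGFL7 with either hairpin (0.13, adjusted p = 0.317, and 0.03, adjusted p = 0.802). Of 4 neuroendocrine and neuronal markers 1 rose with each hairpin: TUBB3 with shEZH2#1 (0.90 ± 0.16) and ENO2 with shEZH2#3 (0.89 ± 0.15). Both rises passed after the correction (0.51, adjusted p = 0.00123, and 0.60, adjusted p = 0.00502). With it TUBB3 was also called lower with shEZH2#3 (-0.80, adjusted p = 4.86e-05). The lists with 3 or 4 tested members were below the minimum of 5 for a list test; adjusted over the list alone, 0 and 2 blood cell markers rose, 2 and 4 endothelial markers rose and 1 fell, 1 and 1 neuronal markers rose, and 0 and 1 class II genes rose.

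The direct test between hairpins called 3311 genes, 1254 higher and 2057 lower with shEZH2#1. EGR1 differed most among genes called in opposite directions that the rule named (-2.71 ± 0.25, adjusted p = 3.34e-07): it had -1.53 ± 0.25 with shEZH2#1 and 1.18 ± 0.22 with shEZH2#3. Lists that differed were those of mitosis (camera adjusted p = 7.6e-07), interferon response, cytokines (0.00101), mesenchymal genes (0.00291), hypoxia and glycolysis (2.12e-05), NRF2 targets (0.0213), ribosomal proteins (0.0153) and mitochondrially encoded genes (7.63e-13). With an estimated correlation none of the 8 passed, with adjusted p from 0.202 to 0.719. Upper quartile scaling turned the split to 2207 higher and 1404 lower, and 1956 genes passed without shEZH2#1 replicate 1.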

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

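Of the tests in this part, those of shluc replicate 2 alone, of the share of cycling cells, of the mitosis level of each library, of the mitosis list in other splits and its count by direction and reference, of the 2 unnamed RNAs, of shEZH2#3 replicate 1 alone and of a library batch, and the GC and length correction, were chosen after the results were seen.

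Several gene groups differed between the hairpins by the direct test of shEZH2#1 against shEZH2#3, with camera at its preset correlation; with an estimated correlation none of the 8 passed (adjusted p = 0.202 to 0.719). The median log2 difference was 0.63 for mitosis genes, 0.57 for interferon response genes and 0.48 for NRF2 targets. It was -0.50 for inflammatory cytokines, -0.50 for mesenchymal genes, -0.48 for hypoxia and glycolysis genes, -0.30 for ribosomal protein genes and -2.28 for mitochondrially encoded genes. Of the 111 genes called in opposite directions, those named by the rule were EGR1 (-2.71 between hairpins), MT-CO1 (-1.90) and MT-CO3 (-1.96).

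Mitosis genes were lower with both hairpins, with a corrected log2 level of 3.94 to 4.45 in the 6 knockdown libraries against 4.63 to 4.69 in shluc. After the GC and length correction the smaller of the medians was -0.32 (bootstrap interval over the list's genes -0.38 to -0.21). Before it, 0% of 10000 random lists matched on GC content, length and expression had medians as low. Both results argue against a GC trend as the whole source. The interval and the random lists draw genes as if independent, and hold no spread between libraries. With an estimated correlation the corrected list passed with shEZH2#3 (camera adjusted p = 0.0308) and not with shEZH2#1 (camera adjusted p = 0.109). Without shluc replicate 2 the larger camera adjusted p was 8.61e-07, at the preset correlation; with an estimated one the calls did not hold (adjusted p = 0.215 and 0.139, and with all 9 libraries 0.201 and 0.133). The mitosis level relative to the replication level was lower by a log2 difference of -0.45 in knockdown libraries (exact permutation test, one-sided p = 0.0119, the smallest that 84 splits can give). The 2 lists were paired after camera had called the first and not the second, so this p-value was not independent of that result. It shows that replication genes fell less than mitosis genes, and cannot decide whether fewer cells were cycling. Chance cannot be excluded by the size of the shift. As large a shift in both contrasts came from 10 of 100 splits (real value 0.50, highest other 0.87). All 10 have at least 2 reference libraries from shluc or from shEZH2#3 and so carry part of the real differences between groups. Of the 10, 3 were falls. Camera at its preset correlation called the mitosis list, with the same sign in both contrasts, in 44 of the 99 other splits. The camera call alone is thus weak evidence. Only 1 of 84 splits of 6 against 3 libraries gave as low a mitosis level, but this was 1 list picked from 35. An effect of lower EZH2 on mitosis genes may be real but stays a hypothesis.

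Mitochondrially encoded RNAs were lower with shEZH2#1 and higher with shEZH2#3, although EZH2 did not differ detectably between the hairpins. After the GC and length correction the smaller size of the list medians was 0.87, which argues against that trend as the whole source. Against dilution by the 2 abundant unnamed RNAs, the mitochondrial share of the remaining counts did not overlap between groups, with a smallest gap of 1.25 percentage points. Without shEZH2#3 replicate 1 the list was still called higher (camera adjusted p = 4.53e-08, median 1.06), though with an estimated correlation it did not hold (adjusted p = 0.206, and 0.564 with all 9 libraries). A difference between the hairpins other than EZH2, or in how the groups were grown or prepared, may remain, and neither was tested.

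GC-rich genes were higher in knockdown libraries, more so with shEZH2#3. Regulation of gene classes and a bias acting on every class cannot be told apart. The slope on GC content within ribosomal protein genes was 1.29 times that over all genes with shEZH2#1 and 0.51 times with shEZH2#3. A bootstrap over these genes, not over libraries, had low ends of 0.83 and 0.21. A library batch that coincides with the groups cannot be told apart from the hairpins either, because per-library correlations with GC content did not overlap between groups (smallest gap 0.12) and no label gives a batch. The correction may also remove regulation that goes with GC content, so calls lost under it, such as those behind the fall from 5861 to 3206 genes with shEZH2#3, are open.

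Other splits of the libraries gave these counts. For each comparison of 2 groups the 10 splits are too few: the real value was 2683 genes for shEZH2#1 against shluc (highest other 1), 5322 for shEZH2#3 against shluc (highest other 0) and 3864 between the hairpins (highest other 0), with 1 split as large in each. For the 6 knockdown libraries against shluc, 2 of 84 splits gave as many genes (real value 1947, highest other 3332). Only splits that kept all 3 groups whole gave more than a few genes, so this count shows that libraries of a group resemble each other. It cannot decide whether the difference between knockdown and control groups arose by chance. The split with 3332 genes sets shEZH2#3 against the other 6 libraries, and shEZH2#1 against the rest gave 210. This points to a structure of 3 distinct groups, and a batch that coincides with them is not excluded. For genes called in both hairpins 1 of 100 splits drawn from 840 was as large (real value 1491, highest other 1253), with the same limit. The 1253 came from the same 3 groups with shEZH2#3 as the reference, so this count shows that the groups are distinct and not that the hairpins share an effect against shluc. For the number of gene lists called in both hairpins 76 of 100 splits gave as many (real value 1, highest other 7), so chance cannot be excluded.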

How the results depend on the processing

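The GC and length correction, the omission of the 2 abundant unnamed genes (with or without the mitochondrial genes) and of the 2 outlying libraries, and an estimated correlation combined with the correction or with libraries left out, were chosen after seeing the data. Counts of genes stayed within 1.5 times under RLE, upper quartile scaling, DESeq2, limma-voom, no filter and a stricter filter. A minimum fold of 2 left 494 genes for shEZH2#1, 1543 for shEZH2#3, 181 in both, 571 for the mean and 918 between hairpins, and left out EZH2 (-0.94, -0.96 and -0.95), because these lie under a size of 1. With the GC and length correction 3206 genes passed for shEZH2#3, 782 in both and 2472 for the mean. Of the named genes called for the mean in either fit, PITX1 (-0.01), XRCC3 (-0.00), MVD (-0.02), H1-2 (-0.08) and TUBB3 (-0.15) changed sign. They have a GC content of 57.5 to 68.9%, and the correction removes the trend with GC content. What caused that trend stays open. Genes called in neither fit, such as KDM6A (-0.16 to 0.29) and SUZ12 (-0.38 to 0.09), could change sign as well. With the 6 knockdown libraries as 1 group 1947 genes passed, since their spread then holds the difference between hairpins. Lists called in both numbered 2 with no filter, 0 with an estimated correlation (mitosis -0.50 and -1.21, adjusted p = 0.201 and 0.133), 7 with fry, 2 with the correction and 0 with the correction and an estimated correlation (mitosis -0.32 and -0.76, adjusted p = 0.109 and 0.0308). Leaving out each library in turn gave 1159 to 3063 genes for shEZH2#1, 4251 to 5823 for shEZH2#3, 657 to 1951 in both, 2649 to 4905 for the mean, 1956 to 3941 between hairpins and 1 to 2 lists. The count in both was 728 without shluc replicate 2, 768 without shEZH2#1 replicate 2 and 657 without shEZH2#1 replicate 3, and that for the mean 2649 without shluc replicate 2. Without shluc replicate 2 and shEZH2#3 replicate 1 the counts were 2240, 4437, 1012, 3292 and 4191. The replicate numbers did not pair the samples (r -0.12 to 0.08, 0 libraries closest to their own number); as a block they gave 2208, 5482, 1285, 4453 and 2938 genes and 1 list. Of the named genes' values for the mean of both hairpins, 2642 kept their side of the threshold, 137 were weaker, 26 stronger and 5 reversed. Calls with single hairpins were not part of this tally. The limma alternatives on normalized values were not run, as the files hold counts. Genes under 0.201 CPM lie below 3 counts in the shallowest library.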

Other observations

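No test of this part was planned: the genes below were chosen after their values were seen. In these libraries, labelled as an esophageal squamous line, KRT5, a basal keratin, had a mean of 0.418 CPM and TP63, a squamous transcription factor, 0.52 CPM, whereas other squamous genes were expressed (ITGB4 at 335 CPM and EVPL at 110 CPM) and the simple epithelial keratins KRT8 and KRT18 had 5630 and 3890 CPM. FOLR1 (7340 CPM), the imprinted RNA H19 (3800 CPM) and the mesenchymal filament VIM (414 CPM) were abundant. These values leave the identity of the line in doubt, and it was not checked here. FOLR1 rose with shEZH2#3 (1.13 ± 0.18, edgeR adjusted p = 0.000123) and had 0.46 ± 0.18 with shEZH2#1 (edgeR adjusted p = 0.0823).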
